A study of Mus musculus with 24 samples.

How the data were processed

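RNA was measured in left and right distal femoral growth plates taken at E17.5 and treated with collagenase to remove soft tissue, per the labels' protocols. The series labels put 12 libraries in 3 groups of 4: WT-wt, from mothers with floxed Eed and no Cre; HET-het, from mothers heterozygous for floxed Eed with Zp3Cre; and HET-hom, from mothers homozygous for floxed Eed with Zp3Cre, all sired by wild type C57BL/6 males. The authors deposited raw counts per gene symbol, with 1 column for each of the 2 lanes of a library, made from the reads without normalization or filtering that the sources state. Per the submitters' processing notes, Trimmomatic 0.39, STAR 2.5.3a and 2.7.5c, featureCounts 1.5.2 and genome build GRCm38 were used, with no role or order stated. The strand setting and annotation release are not given in the sources used here. Lane totals were 17.8 to 25.4 M counts and library totals 35.6 to 50.7 M counts.

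The 2 lanes of a library were summed, because they repeat 1 library. For genes with at least 20 counts over 2 columns, chi-square per degree of freedom was 1.37 to 1.47 between lanes of a library and 6.92 to 61.0 between libraries of a group. Of the 55291 symbols counted, 53180 matched exactly 1 gene of GENCODE release M21, 112 matched several and 1999 none, and coordinates are given only for the first kind. CPM are counts per 1e+06 counts of a library, with totals scaled by TMM (below) for genes and unscaled for shares of markers, given as mean ± SD over 4 libraries, and errors of log2 fold changes are standard errors from the model.

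In R 4.3.3, edgeR 4.0.16 filtered genes by filterByExpr, which left 21788, scaled libraries by TMM (factors 0.939 to 1.09) and fitted a quasi-likelihood negative binomial model with robust dispersion to all 12 libraries, with 1 term per group and 9 residual degrees of freedom. The biological coefficient of variation was 11.6%. The 3 pairwise comparisons and a test of any difference among the groups used Benjamini-Hochberg adjusted p under 0.05, and every gene's adjusted p in the text is edgeR's unless DESeq2 is named. Single values (Eed, shares of markers) were compared by exact two-sided permutation over all 70 arrangements of 4 against 4 libraries, whose smallest p is 0.0286. Adjusted p-values of shares cover 45 tests.

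Gene lists were tested by camera in limma 3.58.1 on the counts of the edgeR model with a preset correlation of 0.01 between genes, adjusted over the 32 lists of a comparison, with an estimated correlation and the fry rotation test as alternatives. With the estimated correlation 1 list passed for HET-hom against HET-het and 0 for the others, where preset camera had called 12, 10 (HET-het against WT-wt) and 19 (HET-hom against WT-wt). fry, which asks whether a list's genes move one way on balance, called 4, 2 and 10. The lists covered resting and articular, proliferating and matrix, and prehypertrophic and hypertrophic chondrocytes. Other cell types were osteoblast, osteoclast, tendon with perichondrium and fibroblast, skeletal muscle, erythroid, immune and myeloid, endothelial, Schwann cell and nerve, adipocyte, and keratinocyte. The rest covered PRC2 and PRC1 subunits, Hox genes, other developmental regulators bound by Polycomb, canonical and noncanonical imprinted genes, hedgehog, Wnt, BMP and TGF-beta, IGF and FGF signalling, cell cycle, hypoxia and glycolysis, immediate early and tissue handling stress, interferon response, unfolded protein response, germline genes, ribosomal proteins and mitochondrially encoded genes. The lists, the named-gene rule and the alternative settings other than those said below to be chosen later were fixed before the data were examined.

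Genes named in the text were Eed, up to 12 rising and 12 falling genes per comparison with the largest log2 fold change among those past the threshold with a mean of at least 1 CPM, leaving out predicted gene models, and up to 4 members of each list with the smallest p among those passing over all genes or over the list alone. The text names a part of these. Genes outside the rule are said to be chosen after their values were seen. Xist and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were read in every library as a label check.

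Alternatives were RLE and upper quartile scaling, DESeq2 1.42.0, limma voom, no filter or a CPM of at least 1 in at least 4 libraries, only the 8 libraries compared, each lane alone, 24 lanes as samples, the replicate number as a block, leaving out each library in turn, and 2 treatments of a number that leads the library names. That leading number is shared by 2 libraries of each group and its meaning is not given in the sources used here. Chosen after the data were seen were a covariate equal to the mean log2 CPM of the endothelial and immune lists, offsets for GC content and exon length, leaving out HET-het replicates 1 and 2 together, and leaving out WT-wt replicate 1 and HET-hom replicate 4 together. The tools and the permutation code were tested on simulated data. No library or lane of the table was left out of the main tests.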

Results

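Transcript levels were measured by RNA sequencing in the distal femoral growth plates of mouse fetuses at stage E17.5 of embryonic development. The growth plate is the cartilage at the end of a long bone in which chondrocytes divide, enlarge and lay down the matrix that lengthens the bone. The fetuses differed in whether the oocyte they came from had carried EED, a core subunit of Polycomb repressive complex PRC2, which places the silencing mark H3K27me3 on histones. WT-wt offspring were wild type and came from oocytes with intact Eed. HET-het offspring carried 1 deleted Eed allele and came from mothers whose Eed deletion in growing oocytes, driven by Zp3Cre, affected 1 allele. HET-hom offspring had the same heterozygous genotype, but their mothers' oocytes had lost both Eed alleles. Each group had 4 libraries, sequenced on 2 lanes that were summed, and all statistics below use n = 4 libraries per group. Library totals ran from 35.6 to 50.7 M counts (M, 1e+06), with group means of 42.0 ± 3.03 M in WT-wt, 41.2 ± 6.63 M in HET-het and 40.7 ± 4.50 M in HET-hom (SD). The labels number the libraries of a group as replicates without saying which litter each came from, so the p-values measure the spread between these libraries. Of the genes in the table, 21788 had enough counts to be tested.

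Eed itself was lower in both heterozygous groups. Eed (chromosome 7, 89954654 to 89980983, minus strand, GRCm38) stood at 20.1 ± 0.879 CPM (counts scaled to a library of 1e+06) in WT-wt, 13.3 ± 0.939 CPM in HET-het and 15.9 ± 0.523 CPM in HET-hom (mean ± SD). HET-het libraries thus held 66.1% and HET-hom libraries 79.0% of the WT-wt level. The log2 fold change against WT-wt was -0.60 ± 0.07 in HET-het (standard error, edgeR adjusted p = 0.00336) and -0.34 ± 0.07 in HET-hom (edgeR adjusted p = 0.0154), and no library of either group overlapped the WT-wt range. HET-hom exceeded HET-het by 0.26 ± 0.07 on the log2 scale (edgeR adjusted p = 0.0416), a call lost in 10 of the 12 refits that each left out 1 library. In these the log2 fold change ran from 0.21 to 0.29. Without HET-hom replicate 4 the difference between HET-hom and WT-wt was -0.33 and no longer passed. An exact two-sided permutation test gave p = 0.0286 for each of the 3 pairs of groups, the smallest value that 4 against 4 libraries allow. Counts were summed over the whole gene, so reads from exons outside the deletion are included. Xist, the RNA that coats the inactive X chromosome of females, was at 2177 to 3102 CPM in the 12 libraries, and no library held more than 6 counts of any of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty.

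**Figure D1:**
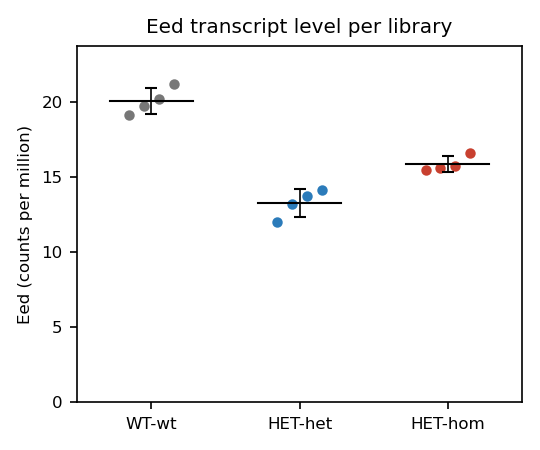
Eed transcript level in CPM for each of the 12 libraries, by group, where points are libraries, long bars are means and error bars are SD. HET-het (mean 13.3) and HET-hom (mean 15.9) lie below every WT-wt library (mean 20.1), and HET-hom lies above HET-het.

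HET-hom and HET-het offspring have the same genotype, so their comparison was designed to isolate the loss of EED in the oocyte. The gene with the largest rise among those with at least 1 CPM was Bcl6 (chromosome 16, 23965052 to 23988852, minus strand), which encodes a transcriptional repressor: 12.2 ± 4.43 CPM in HET-hom against 3.61 ± 0.155 in HET-het, a 3.39-fold difference (edgeR adjusted p = 0.00176). Scn9a, a voltage-gated sodium channel gene (chromosome 2, 66480080 to 66634962, minus strand), rose from 0.895 ± 0.0920 to 2.58 ± 0.559 CPM, and Fyb, St8sia6, Cfap44 and B3gnt5 rose between 2.07-fold and 2.22-fold. Among genes that fell, Prg4, which encodes the joint lubricant lubricin (chromosome 1, 150449412 to 150466165, minus strand), was at 29.0 ± 9.04 CPM in HET-hom and 103 ± 25.5 in HET-het. Serpine1, the gene of plasminogen activator inhibitor 1 (chromosome 5, 137061504 to 137072268, minus strand), was at 16.6 ± 2.32 CPM against 50.6 ± 7.22. For Serpine1 HET-het was also above WT-wt, and for Cfap44 it was below WT-wt (both given below). At least a part of these 2 differences therefore lies in HET-het. Prg4 fell less against WT-wt, with log2 fold changes in HET-hom of -1.33 to -0.92 over the alternative settings. That call was lost in 19 of the 29 settings. Clic5, Igfals, Casr and Gbp7 also fell, with log2 fold changes of -2.20, -1.93, -1.89 and -1.83, and Sele fell from 3.06 ± 0.635 to 0.771 ± 0.419 CPM. Igfals encodes a partner of circulating insulin-like growth factor (IGF), Casr the calcium-sensing receptor and Sele the endothelial adhesion molecule E-selectin. Xlr3b fell from 3.82 ± 0.765 to 0.671 ± 0.0390 CPM, but it belongs to a family of near-identical X-linked copies and its counts are uncertain. Each of these genes kept its call in all 12 refits that left out 1 library, and without HET-het replicates 1 and 2 together only that of Cfap44 was lost (adjusted p = 0.0570).

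In all, 1385 genes changed between HET-hom and HET-het at an adjusted p under 0.05 in edgeR's quasi-likelihood test, 650 of them higher and 735 lower in HET-hom. Changes of more than 2-fold were mostly losses, with 149 genes lower and 28 higher, and the median absolute log2 fold change of the changed genes was 0.42. The count fell to 658, 729 and 712 without HET-het replicates 1, 2 and 3, and to 638 and 665 without HET-hom replicates 2 and 4, while DESeq2 called 2117 genes. In each group 2 libraries share a leading number in their names, and the count was 573 with such libraries summed and 726 with that number as a random block. With the mean level of endothelial and immune markers as a covariate, a fit chosen after the data were seen, 403 genes passed and all 1385 kept their sign. Their median absolute log2 fold change went from 0.42 to 0.38 and the median of their single-gene standard errors from 0.0926 to 0.104.

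**Figure D2:**
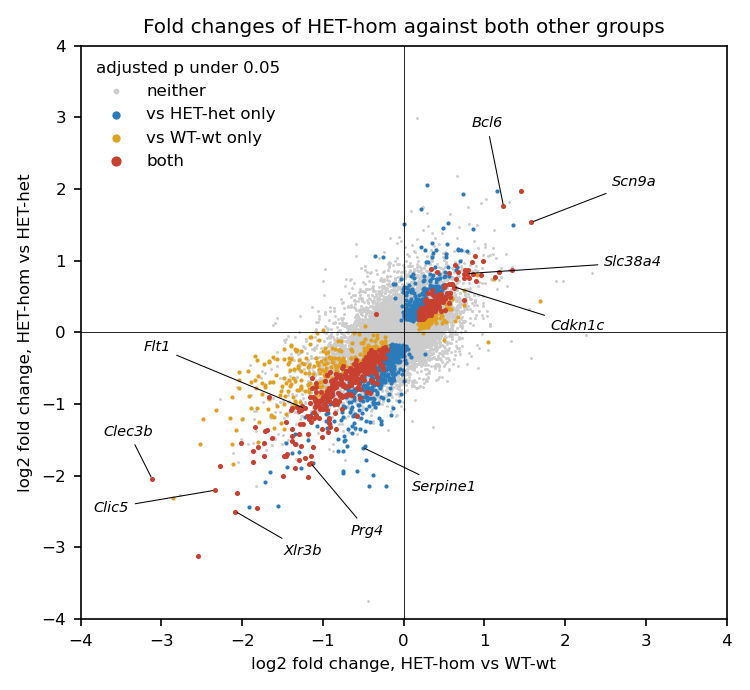
Log2 fold changes of the 21788 tested genes in HET-hom against WT-wt (horizontal axis) and against HET-het (vertical axis), with each point a gene, coloured by where its adjusted p was under 0.05, and with 2 genes outside the axes. Both axes share the HET-hom libraries, and 448 genes passed in the same direction on both.

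Noncanonical imprinting is a form of parental imprinting that rests on maternal H3K27me3 in the oocyte. Of 15 tested genes of this kind, 5 rose in HET-hom over all genes and 7 when adjusted over the list alone, and none fell. By sign 12 were higher and 3 lower. The list passed camera, which compares its genes with all others (adjusted p = 1.1e-05, and adjusted p = 0.278 with an estimated correlation). Slc38a4, an amino acid transporter gene (chromosome 15, 96994820 to 97055956, minus strand), was at 182 ± 23.8 CPM in HET-hom and 103 ± 13.9 in HET-het, a log2 fold change of 0.82 ± 0.10 (edgeR adjusted p = 0.000427). Enc1, which encodes an actin-binding protein (chromosome 13, 97241105 to 97253034, plus strand), was at 99.1 ± 8.38 CPM against 68.1 ± 1.06 (edgeR adjusted p = 0.000211). Otogl and Bbx rose by 0.75 and 0.21 on the log2 scale, as did Smoc1 by 0.39, named after its value was seen, but the calls of Otogl and Bbx were lost in 6 and 5 of the 12 refits without 1 library. Smoc1 averaged 113 CPM in HET-hom, 86.3 in HET-het and 102 in WT-wt. Against WT-wt its log2 fold change in HET-hom was 0.145 and did not pass (edgeR adjusted p = 0.424). Enc1 averaged 77.8 CPM in WT-wt, also above HET-het. Sfmbt2, Gab1 and Jade1, members of the same list named after their values were seen, had log2 fold changes of 0.09, 0.01 and 0.08 and did not pass. Canonical imprinted genes, whose silencing rests on DNA methylation, did not pass as a list (median log2 fold change 0.01, camera adjusted p = 0.506), with 3 of 43 higher and 2 lower over all genes and 4 each way adjusted over the list alone. Cdkn1c, which encodes the cell cycle inhibitor p57 (chromosome 7, 143458339 to 143461050, minus strand), was nonetheless higher by 0.64 ± 0.08 (681 ± 74.2 CPM against 439 ± 38.7, edgeR adjusted p = 0.000427). Peg10 rose by 0.41 and the maternally expressed noncoding RNA Meg3 fell by 0.58, and the calls of all 3 held in each of the 12 refits. Meg3 lost its call in 4 other settings, without a filter (adjusted p = 0.0634), with libraries of a shared leading number summed (0.0575), with the marker covariate (0.0696) and without HET-het replicates 1 and 2 (0.157).

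**Figure D3:**
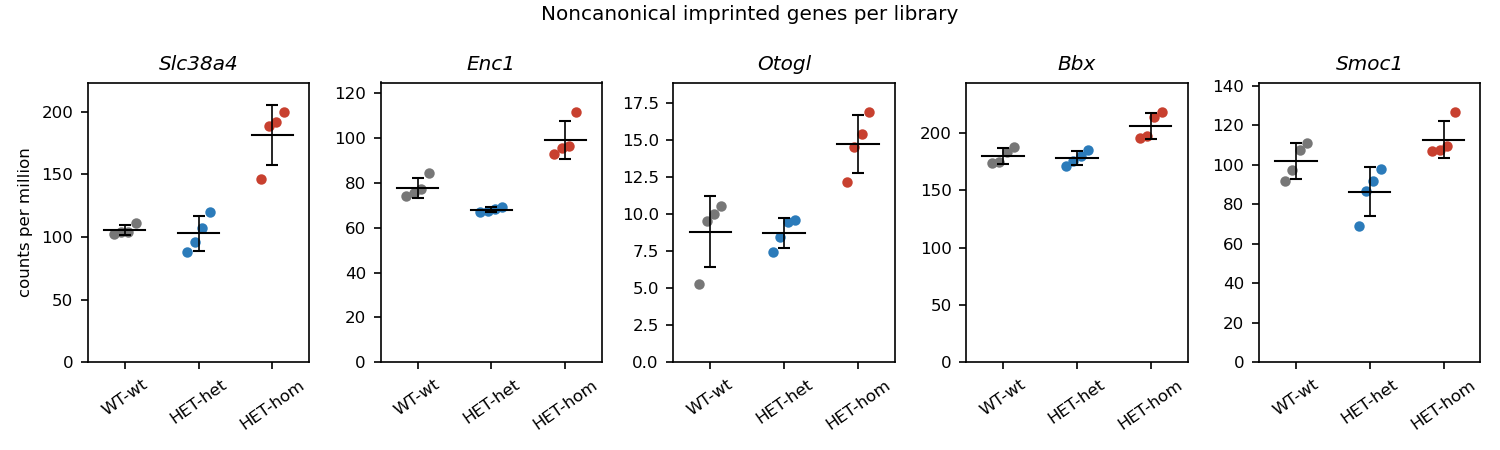
Levels in CPM of the 5 noncanonical imprinted genes called higher in HET-hom than in HET-het, for each of the 12 libraries, with means as long bars and SD as error bars. For Slc38a4 the HET-hom mean is 182, against 106 in WT-wt and 103 in HET-het.

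Of the 5 lists of signalling genes, those of the IGF, FGF and BMP with TGF-beta pathways were lower in HET-hom by camera and those of Wnt and hedgehog did not pass. In the IGF list 5 of 17 members fell over all genes and 6 adjusted over the list alone, with a median log2 fold change of -0.34, and this list alone kept its call with an estimated correlation (camera adjusted p = 2.33e-05, and adjusted p = 0.0322 with an estimated correlation). Pappa2 (chromosome 1, 158711727 to 158980490, minus strand) was at 116 ± 10.4 CPM against 184 ± 9.25. Against WT-wt its log2 fold change in HET-hom was smaller, at -0.33 to -0.19 over the alternative settings. It encodes a protease that frees IGF from its binding proteins. Igfbp7, Igfbp6 and Igfbp3, which encode such binding proteins, fell by 0.94, 1.05 and 1.41 on the log2 scale, with the Igfbp3 call lost in 8 of the 12 refits and that of Igfbp6 in 1, without HET-hom replicate 4. In the FGF list 4 of 18 members fell over all genes and 5 adjusted over the list alone, among them Dusp6 (-0.54 ± 0.08) and Spry4 (-0.47 ± 0.12), both feedback inhibitors that the pathway induces (camera adjusted p = 0.0310, and adjusted p = 0.481 with an estimated correlation). The Spry4 call was lost in 6 of the 12 refits, and the list did not pass without HET-het replicate 3 (adjusted p = 0.105) or HET-hom replicate 1 (adjusted p = 0.0850), nor with the marker covariate (adjusted p = 0.204). The BMP and TGF-beta list was lower (camera adjusted p = 0.00237, and adjusted p = 0.383 with an estimated correlation), though not without HET-hom replicate 1 (adjusted p = 0.0735), with 4 of 29 members lower and 3 higher over all genes, and 8 and 3 adjusted over the list alone. Besides Serpine1, Bmp3 and Smad6 fell by 0.54 and 0.34, and Chrdl1, a BMP antagonist gene, rose by 0.82. The calls of Smad6 and Chrdl1 were lost without HET-het replicate 1 or HET-hom replicate 2, and without HET-het replicate 2. That of Chrdl1 was also lost with libraries of a shared leading number summed (adjusted p = 0.0735). The Wnt list had a camera adjusted p of 0.361, yet Lef1 and Wnt5a rose by 0.37 and 0.46, and the inhibitor genes Wif1 and Sfrp2 fell by 0.55 and 0.50. The Wnt5a call was lost in 6 of the 12 refits. With libraries of a shared leading number summed the calls of Wnt5a and Sfrp2 were lost (adjusted p = 0.0544 and 0.0524). The Wnt list had 3 of 20 members higher and 2 lower over all genes, and 3 and 4 adjusted over the list alone. Of the 12 hedgehog genes 2 rose over all genes, and 2 rose and 2 fell adjusted over the list alone: the hedgehog receptor and target gene Ptch1 rose by 0.32 ± 0.07, and Gli3 by 0.21 ± 0.05 (camera adjusted p = 0.723 for the list). The Gli3 call was lost in 6 of the 12 refits and with libraries of a shared leading number summed (adjusted p = 0.0676).

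Among chondrocyte genes, the resting and articular list was lower, with 4 of 14 members lower and 1 higher over all genes, and 8 and 2 adjusted over the list alone (camera adjusted p = 0.00203, and adjusted p = 0.383 with an estimated correlation). Prg4, Wif1 and the cartilage matrix gene Ucma fell by 1.83, 0.55 and 1.65 on the log2 scale, and Sfrp5 rose by 0.42. The Ucma call was lost in 4 of the 12 refits and that of Sfrp5 without HET-het replicate 3. The proliferating chondrocyte and matrix list passed upward on small shifts, with a median log2 fold change of 0.04 (camera adjusted p = 0.0326, and adjusted p = 0.761 with an estimated correlation). Its 2 called members of 25, over all genes and over the list alone, were Prelp (0.35 ± 0.07) and the chondrocyte transcription factor gene Sox5 (0.29 ± 0.06). This list did not pass without HET-het replicate 1, 2 or 3 or without HET-hom replicate 3 or 4 (adjusted p = 0.0591, 0.199, 0.0741, 0.074 and 0.301). The resting list did not pass with the marker covariate (adjusted p = 0.161), and the proliferating list turned downward without passing (adjusted p = 0.801). Prehypertrophic and hypertrophic genes did not pass as a list (median 0.05, camera adjusted p = 0.669). Of 17 members 2 fell over all genes, and 2 fell and 2 rose adjusted over the list alone. Cell cycle genes were higher in all 30 of 30 members by sign, and 8 passed over all genes and 14 adjusted over the list alone (median 0.14, camera adjusted p = 1.36e-08, and adjusted p = 0.383 with an estimated correlation). Ccne1, which encodes cyclin E1, rose by 0.52 ± 0.08 and Tyms, which makes thymidylate for DNA synthesis, by 0.35 ± 0.07.

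Markers of several cell types other than chondrocytes also differed between HET-hom and HET-het, and by camera the endothelial and fibroblast lists passed. All 13 endothelial genes were lower in HET-hom by sign, with 2 past the test over all genes and 9 adjusted over the list alone (median -0.76, camera adjusted p = 1.62e-07, and adjusted p = 0.383 with an estimated correlation). Flt1, a receptor for vascular endothelial growth factor, fell by 1.06 and Eng by 0.72, calls lost in 8 and 4 of the 12 refits. Both calls were also lost with libraries of a shared leading number summed (adjusted p = 0.106 and 0.0547). Endothelial markers took 220 ± 66.2 CPM in HET-hom, 353 ± 39.5 in HET-het and 422 ± 125 in WT-wt, and osteoblast markers took 15122 ± 2190, 24621 ± 4706 and 24566 ± 6835. For both shares HET-hom differed from HET-het at p = 0.0286 in an exact permutation test, the smallest value possible, and at an adjusted p of 0.0918 over the 45 share tests. The osteoclast, skeletal muscle and adipocyte shares were lower at the same 2 p-values. The fibroblast share was 6775 ± 513 CPM against 8201 ± 897 (exact permutation p = 0.0571). The Schwann cell share was higher, at 1.24 of HET-het (exact permutation p = 0.0571). Erythroid and keratinocyte shares did not differ (exact permutation p = 0.571 and 0.714). Tendon, perichondrium and fibroblast genes fell too, with 2 of 15 lower over all genes, and 7 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.00104, and adjusted p = 0.406 with an estimated correlation, and 0.158 with the marker covariate), whereas immune markers took 32.9 ± 4.40 and 32.7 ± 3.16 CPM (exact permutation p = 0.971). Handling stress genes were lower in HET-hom, with 2 of 25 passing over all genes and 9 adjusted over the list alone (camera adjusted p = 0.00104, and adjusted p = 0.618 with an estimated correlation), and Fosb fell by 1.35. In the same list the heat shock gene Hspa1b was at 540 and 227 CPM in HET-het replicates 1 and 2, against 5.12 to 30.9 CPM in the other 10 libraries. Without these 2 libraries 372 genes changed, 339 of them among the 1385, and leaving out any other pair of HET-het libraries left 168 to 674. The calls of Ptch1, Lef1, Sfrp2, Sox5, Tbx15 and Fosb were among those lost without them (adjusted p = 0.0669 to 0.147). Among those that the marker covariate ended were the calls of Ptch1, Lef1, Sfrp2, Sox5, Prelp, Igfbp7, Sparc and Fosb (adjusted p = 0.0584 to 0.122). Others were those of Igfbp6, Pfkfb3, Spry4, Smad6, Chrdl1, Gli3, Ucma and Sox10 (adjusted p = 0.114 to 0.209). Fold changes moved by unlike amounts, with log2 values under the covariate of -1.48 for Fosb, 0.33 for Lef1, -0.23 for Spry4 and 0.17 for Pfkfb3. With libraries of a shared leading number summed the Fosb call was lost too (adjusted p = 0.0786).

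**Figure D4:**
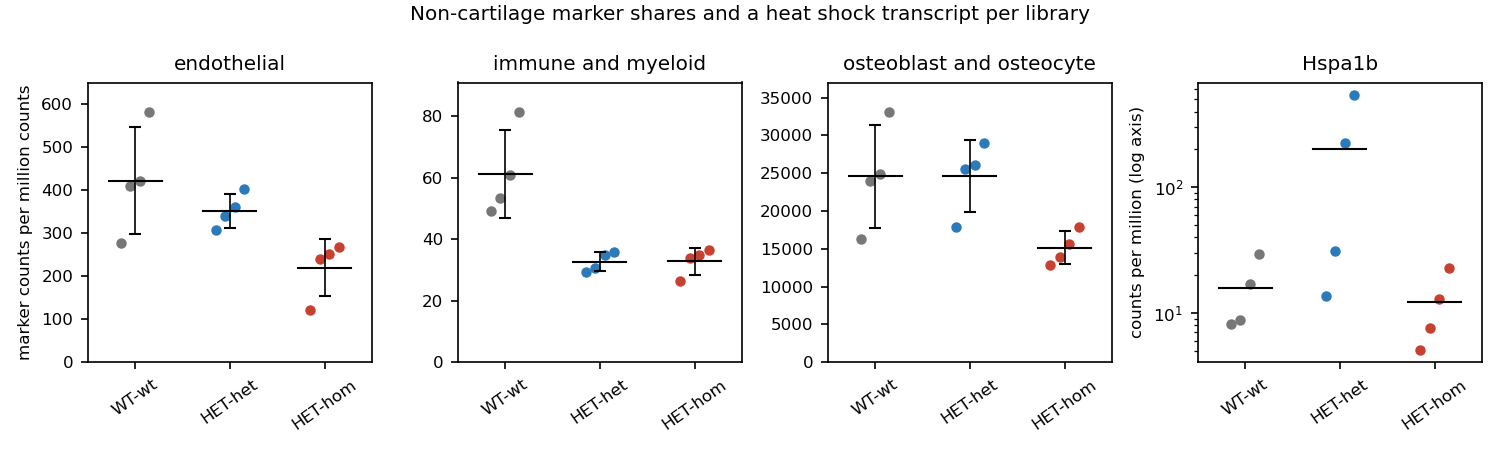
Share of counts taken by endothelial, immune and osteoblast marker genes (CPM, linear axes) and Hspa1b level (CPM, logarithmic axis) in each of the 12 libraries, with means as long bars and SD as error bars on the linear axes. Endothelial markers average 220 in HET-hom against 353 in HET-het, and Hspa1b reaches 540 and 227 in 2 HET-het libraries.

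Genes of Polycomb itself gave a mixed picture. Besides Eed, the PRC2 subunit genes Jarid2 and Mtf2 rose by 0.28 and 0.23 on the log2 scale, with calls lost in 5 and 7 of the 12 refits, and Ezh1, which encodes an alternative catalytic subunit, fell by 0.33 ± 0.07 with its call kept in all 12. Ezh1 lost it with libraries of a shared leading number summed (adjusted p = 0.0593), with the marker covariate (0.0789) and without HET-het replicates 1 and 2 (0.0979). Of the 12 PRC2 genes 3 rose and 1 fell over all genes, and 6 and 1 adjusted over the list alone (camera adjusted p = 0.119 for the list, and 0.0115 by the rotation test fry). Of the 19 PRC1 genes 1 rose over all genes, Rybp, and 2 adjusted over the list alone (camera adjusted p = 0.270). Among 51 other developmental regulators bound by Polycomb, 3 rose and 1 fell over all genes, and 3 and 2 adjusted over the list alone (camera adjusted p = 0.669). Shox2, a homeobox gene of limb cartilage, rose by 0.36 ± 0.06 and Tbx15 by 0.25 ± 0.05. Of 29 Hox genes 1 rose over all genes, Hoxa2, and 1 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.0944). The calls of Rybp and Hoxa2 were lost in 7 and 6 of the 12 refits. Of 6 germline genes that somatic cells keep silent, none passed over all genes and 1 fell adjusted over the list alone (camera adjusted p = 0.270).

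Mitochondrially encoded genes were lower as a list, with 0 of 16 members past the test over all genes or adjusted over the list alone (median -0.25, camera adjusted p = 0.00202, and adjusted p = 0.406 with an estimated correlation), a call lost without HET-het replicates 1 and 2 together (adjusted p = 0.234). The interferon response list was lower, with 1 of 19 members called over all genes and adjusted over the list alone (camera adjusted p = 0.0334, and adjusted p = 0.618 with an estimated correlation). It did not pass without HET-het replicate 1 or 2 or HET-hom replicate 1 or 4 (adjusted p = 0.169, 0.119, 0.0558 and 0.0932), nor with the marker covariate (adjusted p = 0.640). Osteoblast and skeletal muscle lists lay just over the threshold (camera adjusted p = 0.05001 each). Of 12 osteoblast genes 1 fell over all genes and 3 adjusted over the list alone, among them Sparc (-0.50 ± 0.11), and of 12 muscle genes 1 rose and 2 fell over all genes, and 1 and 3 adjusted over the list alone. No camera call was made for osteoclast (7 tested, adjusted p = 0.361), erythroid (4, 0.613), immune and myeloid (11, 0.669), Schwann cell and nerve (10, 0.952), adipocyte (2, 0.0750) or keratinocyte (7, 0.541) markers. Among them Sox10 rose and Fabp4 fell over all genes, each call lost in 6 of the 12 refits. Adjusted over the list alone 1 Schwann cell gene rose and 1 gene each of the osteoclast and adipocyte lists fell. For erythroid genes the median (-0.11) and the mean (0.02) differed in sign, and so did the hedgehog median (0.03) and mean (-0.02). Hypoxia and glycolysis genes did not pass as a list (camera adjusted p = 0.389), with 1 of 24 higher and 3 lower both over all genes and adjusted over the list alone. In that list Ndrg1 fell by 0.89 ± 0.13 and the glycolytic regulator gene Pfkfb3 rose by 0.31 ± 0.07, a call lost without HET-het replicate 3 or HET-hom replicate 4. None of 18 genes of the unfolded protein response passed over all genes or adjusted over the list alone (camera adjusted p = 0.723). Of 85 ribosomal protein genes 1 fell over all genes, Rpl22l1, with its call lost in 6 of the 12 refits, and 0 adjusted over the list alone (camera adjusted p = 0.0750).

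**Figure D5:**
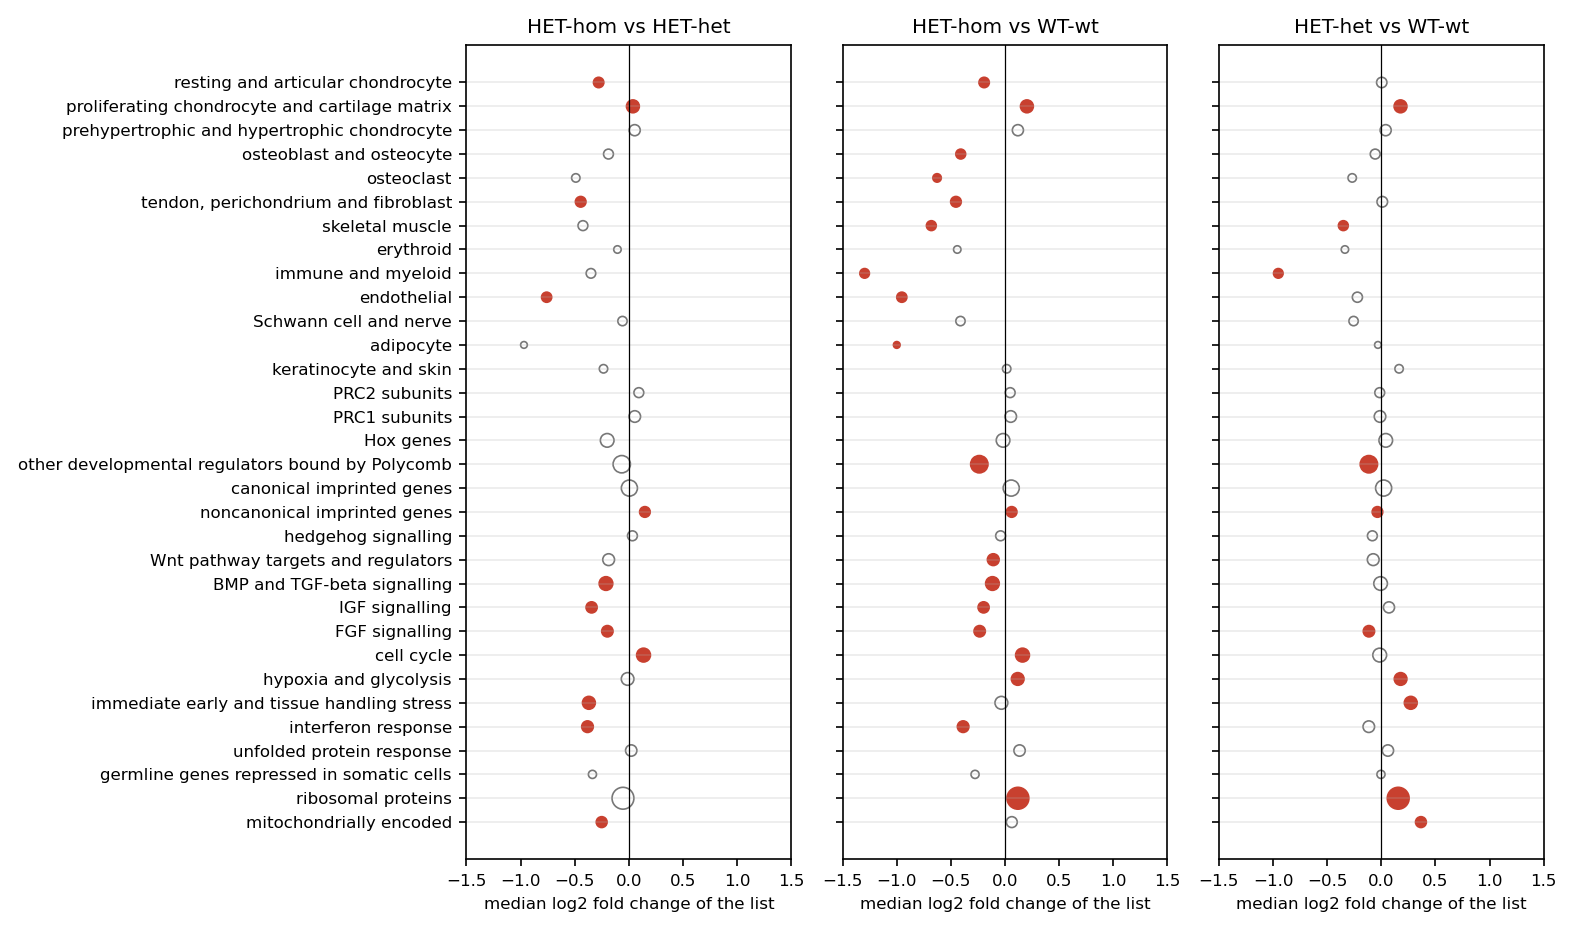
Median log2 fold change of each of the 32 gene lists in the 3 comparisons, with each circle a list, its area growing with the number of genes tested, filled where camera's adjusted p was under 0.05 and open otherwise. The endothelial list lies at -0.76 in HET-hom against HET-het, -0.22 in HET-het against WT-wt and -0.95 in HET-hom against WT-wt.

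The comparison of HET-hom with WT-wt adds the offspring's own heterozygosity to the loss of oocyte EED. Clic5 fell by 2.34 on the log2 scale and Scn9a rose by 1.58, as they had against HET-het. Dmrta1, a transcription factor gene, was at 4.33 ± 0.421 CPM in HET-hom and 1.91 ± 0.0971 in WT-wt (log2 fold change 1.18 ± 0.18, edgeR adjusted p = 0.00311), and Apela and St8sia1 rose by 1.34 and 0.85. The collagen gene Col22a1 fell by 1.84 and Clec3b by 3.12, and all of these genes kept their calls in each of the 12 refits without 1 library but not with the marker covariate. Over all alternatives, the covariate included, log2 fold changes were -2.66 to -2.01 for Clic5, -2.03 to -1.63 for Col22a1 and -3.60 to -2.12 for Clec3b. They were 0.93 to 1.81 for Scn9a, 1.02 to 1.35 for Dmrta1, 0.90 to 1.55 for Apela and 0.49 to 0.93 for St8sia1. Bcl6 rose by 1.24, a call lost without HET-hom replicate 4. In all, 837 genes changed (edgeR adjusted p under 0.05), 270 higher and 567 lower, and 207 of the genes that fell but 9 of those that rose changed by more than 2-fold. DESeq2 called 1582 genes and edgeR 419 when fitted to the 8 libraries of the comparison. The count was 520 with libraries of a shared leading number summed and 447 with that number as a random block. It was 477, 467 and 478 without WT-wt replicates 1, 3 and 4 and 329 and 219 without HET-hom replicates 2 and 4. With the endothelial and immune marker covariate edgeR called 0 genes, with 1590 at an unadjusted p under 0.05. The median absolute log2 fold change of the 837 went from 0.60 to 0.28 and the median of their single-gene standard errors from 0.13 to 0.18.

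Markers of 7 other cell types were lower in HET-hom than in WT-wt by camera with its preset correlation, and none of the 7 lists passed with an estimated one. All 13 of 13 endothelial genes were lower when adjusted over the list alone, 4 of them over all genes (median -0.95, camera adjusted p = 3.05e-12, and adjusted p = 0.244 with an estimated correlation). Flt1 and Eng fell by 1.22 and 0.75, with calls lost in 5 refits each. Of 11 immune and myeloid genes 6 fell over all genes and 9 adjusted over the list alone (camera adjusted p = 5.23e-11, and adjusted p = 0.0856 with an estimated correlation). The macrophage genes Mrc1, Lyz2 and Csf1r fell by 1.66, 1.62 and 1.42, and their calls held in all 12 refits but not with the marker covariate. Skeletal muscle genes fell in 2 of 12 cases over all genes, and 7 fell and 1 rose adjusted over the list alone (camera adjusted p = 8.43e-05, and adjusted p = 0.0856 with an estimated correlation), with Ttn, the gene of the muscle protein titin, lower by 0.80 ± 0.16. Without HET-hom replicate 4 its log2 fold change was -0.79 and the call was lost. In the tendon, perichondrium and fibroblast list 1 of 15 fell and 1 rose over all genes, and 8 and 1 adjusted over the list alone (camera adjusted p = 0.000100, and adjusted p = 0.293 with an estimated correlation). Osteoclast genes were lower, with 1 of 7 called over all genes, Itgb3, and 2 adjusted over the list alone (camera adjusted p = 0.00656, and adjusted p = 0.293 with an estimated correlation). Osteoblast genes were lower with 0 of 12 called over all genes and 2 adjusted over the list alone (camera adjusted p = 0.00812, and adjusted p = 0.416 with an estimated correlation). That list did not pass without WT-wt replicate 4 (adjusted p = 0.0666) or HET-hom replicate 1 (adjusted p = 0.117). Of the 2 adipocyte genes 1 fell, Fabp4, over all genes and adjusted over the list alone (camera adjusted p = 0.0402, and adjusted p = 0.256 with an estimated correlation), a list call lost without WT-wt replicate 1, 3 or 4 or HET-hom replicate 1 (adjusted p = 0.0930, 0.0612, 0.0505 and 0.145). The calls of Itgb3 and Fabp4 were lost in 8 refits each. With the marker covariate the fibroblast, osteoblast and osteoclast lists turned upward without passing (adjusted p = 0.818, 0.891 and 0.962), and the adipocyte list did not pass (adjusted p = 0.962). That covariate is the mean of the endothelial and immune lists, so it removes their own change by construction. The endothelial list then passed upward (adjusted p = 0.0494). The share of immune markers was 32.9 ± 4.40 CPM in HET-hom and 61.1 ± 14.2 in WT-wt (exact permutation p = 0.0286, the smallest possible, adjusted p = 0.0918).

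The lists of proliferating chondrocyte and matrix genes, cell cycle genes and noncanonical imprinted genes were higher in HET-hom than in WT-wt by camera with its preset correlation, beside these lower markers. With the marker covariate the cell cycle list stayed called (adjusted p = 1.73e-07), but the matrix and noncanonical imprinted lists turned downward without passing (adjusted p = 0.993 and 0.962). In the proliferating chondrocyte and matrix list 4 of 25 members rose over all genes and 10 adjusted over the list alone (median 0.20, camera adjusted p = 1.49e-09, and adjusted p = 0.293 with an estimated correlation). Prelp rose by 0.35 ± 0.07 and the proteoglycan gene Epyc by 0.55 ± 0.12, the latter lost without WT-wt replicate 4 or HET-hom replicate 1 or 4. Of the 30 cell cycle genes 3 rose over all genes, Ccne1 among them (0.43 ± 0.08), and 14 adjusted over the list alone (camera adjusted p = 1.49e-09, and adjusted p = 0.293 with an estimated correlation). In the noncanonical imprinted list 4 of 15 members rose and 1 fell, both over all genes and adjusted over the list alone (camera adjusted p = 0.00370, and adjusted p = 0.293 with an estimated correlation). Slc38a4 rose by 0.78 ± 0.10 (182 ± 23.8 CPM against 106 ± 3.71) and Enc1 by 0.35 ± 0.06. Otogl rose by 0.74 and Prox1 fell by 0.82, calls lost in 6 and 8 of the refits, and Bbx, named for this comparison after its value was seen, rose by 0.20. Canonical imprinted genes rose in 4 of 43 cases over all genes, and 5 rose and 3 fell adjusted over the list alone. The list did not pass camera (adjusted p = 0.0684) but passed fry, which asks for a move one way on balance (adjusted p = 0.0346). Cdkn1c rose by 0.62 ± 0.08 and Peg10 by 0.40 ± 0.07. Hypoxia and glycolysis genes were higher, with 2 of 24 up and 1 down over all genes and adjusted over the list alone (camera adjusted p = 0.00526, and adjusted p = 0.550 with an estimated correlation). Pfkfb3 rose by 0.52 ± 0.07 and Ndrg1 fell by 0.75 ± 0.13, and the list did not pass without WT-wt replicate 1 (adjusted p = 0.0784) or 4 (adjusted p = 0.0505) and turned downward without passing with the covariate (adjusted p = 0.0767). Ribosomal protein genes were higher, with 1 of 85 called over all genes, Rps27l, a call lost in 4 of the 12 refits, and 0 adjusted over the list alone (camera adjusted p = 2.17e-08, and adjusted p = 0.423 with an estimated correlation). Their share of counts was 19101 ± 879 CPM in HET-hom and 17805 ± 1452 in WT-wt (exact permutation p = 0.2). WT-wt replicate 2 held 15643 CPM and the other WT-wt libraries 18341 to 18758.

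Of the 5 signalling lists, 4 were lower in HET-hom than in WT-wt by camera with its preset correlation, and none of them passed with an estimated correlation or with the marker covariate. The hedgehog list did not pass (camera adjusted p = 0.460), with 1 of 12 members lower over all genes, and 2 higher and 2 lower adjusted over the list alone. In the FGF list 6 of 18 members fell over all genes and 8 adjusted over the list alone (camera adjusted p = 1.92e-05, and adjusted p = 0.244 with an estimated correlation), with Dusp6 at -0.56 ± 0.08 and Spry1 at -0.83 ± 0.17, the latter lost without HET-hom replicate 4. In the IGF list 1 of 17 fell over all genes, Igfbp6 at -1.38, and 7 adjusted over the list alone (camera adjusted p = 0.00200, and adjusted p = 0.0856 with an estimated correlation). The BMP and TGF-beta list was lower, with 4 of 29 down and 1 up over all genes, and 10 and 3 adjusted over the list alone (camera adjusted p = 0.0196, and adjusted p = 0.381 with an estimated correlation), and it was not called without HET-hom replicate 1 (adjusted p = 0.270). Bmp3 fell by 0.46 ± 0.08. The Wnt list was lower, with 3 of 20 down over all genes, and 4 down and 1 up adjusted over the list alone (camera adjusted p = 0.0439, and adjusted p = 0.477 with an estimated correlation). It did not pass without WT-wt replicate 1 or HET-hom replicate 1 or 3 (adjusted p = 0.226, 0.259 and 0.0914). Of 51 other Polycomb-bound regulators 4 fell and 1 rose over all genes, and 8 and 1 adjusted over the list alone (camera adjusted p = 0.00370, and adjusted p = 0.293 with an estimated correlation). The list did not pass with the marker covariate (adjusted p = 0.912). Gata6 fell by 1.72 ± 0.36 and Shox2 rose by 0.38 ± 0.06. The resting and articular list was lower, with 3 of 14 down and 1 up over all genes, and 5 and 1 adjusted over the list alone (camera adjusted p = 0.0214, and adjusted p = 0.381 with an estimated correlation). It did not pass without WT-wt replicate 1 or 4 or HET-hom replicate 1 (adjusted p = 0.171, 0.0505 and 0.0819), and in it Sfrp5 rose by 0.49 ± 0.09. Interferon response genes were lower as a list, with 0 of 19 called over all genes or adjusted over the list alone (camera adjusted p = 0.00812, and adjusted p = 0.416 with an estimated correlation). The resting and interferon lists turned upward without passing when the marker covariate was added (adjusted p = 0.428 and 0.818). In the handling stress list, which did not pass (camera adjusted p = 0.341), Egr3 fell by 1.07 ± 0.14. The keratinocyte median (0.01) and mean (-0.05) differed in sign, as did the PRC2 median (0.05) and mean (-0.02), and neither list passed.

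HET-het against WT-wt measures the offspring's heterozygosity, with oocytes that kept Eed in WT-wt mothers and came from heterozygous mothers in HET-het. Apart from Eed, Cfap44, a gene of the ciliary axoneme, fell by 1.42 ± 0.18 on the log2 scale (2.08 ± 0.428 CPM in HET-het, 5.62 ± 1.24 in WT-wt, edgeR adjusted p = 0.00354), and Inka2 fell by 0.54 ± 0.07. Inka2 and Cfap44 rose in HET-hom against HET-het by 0.88 and 1.07. Serpine1 rose by 1.11 ± 0.15, and Oplah and Odc1, the gene of the polyamine enzyme ornithine decarboxylase, by 0.55 and 0.41, but these 3 calls were lost in 6, 7 and 10 of the 12 refits. The predicted genes Gm49759 and Gm26461, named after their values were seen, rose by 0.57 and 0.97. The calls of Cfap44 and Inka2 were lost with libraries of a shared leading number summed (adjusted p = 0.0587 and 0.0907) and without HET-het replicates 1 and 2 (adjusted p = 0.106 and 0.120). These 8 genes, 5 higher and 3 lower, were all that changed by edgeR at an adjusted p under 0.05, while 2533 genes had an unadjusted p under 0.05 and DESeq2 called 154. The count was 3 with libraries of a shared leading number summed and 5 with that number as a random block. It was 13 without WT-wt replicate 2, 3 without WT-wt replicate 3 or 4 or HET-het replicate 3, and 5 without HET-het replicate 2.

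Immune and myeloid genes were lower in HET-het than in WT-wt, with 0 of 11 members called over all genes and 8 adjusted over the list alone (median -0.95, camera adjusted p = 2.31e-15, and adjusted p = 0.0771 with an estimated correlation). Mrc1 had a log2 fold change of -1.25 ± 0.23 and Lyz2 of -1.27 ± 0.29, and both passed over the list alone. Mitochondrially encoded genes were higher, with 0 of 16 over all genes and 7 adjusted over the list alone (median 0.37, camera adjusted p = 1.74e-10, and adjusted p = 0.195 with an estimated correlation). Their share of counts was 7871 and 7459 CPM in HET-het replicates 1 and 2. In HET-het replicates 3 and 4 it was 5423 and 5506 CPM, inside the WT-wt range of 5108 to 6071. The groups did not differ in this share (exact permutation p = 0.171). Ribosomal protein genes were higher, with 0 of 85 over all genes and 12 adjusted over the list alone (median 0.16, camera adjusted p = 1.08e-23, and adjusted p = 0.413 with an estimated correlation). The proliferating chondrocyte list passed upward with 0 of 25 members called over all genes or adjusted over the list alone (camera adjusted p = 1.36e-05, and adjusted p = 0.547 with an estimated correlation), though not without WT-wt replicate 1 (adjusted p = 0.0512). Hypoxia and glycolysis genes did so too, with 0 of 24 called either way (camera adjusted p = 4.84e-07, and adjusted p = 0.497 with an estimated correlation). Handling stress genes were higher as a list, with 0 of 25 called over all genes and 1, Egr3, lower when adjusted over the list alone (camera adjusted p = 0.000957, and adjusted p = 0.684 with an estimated correlation). That call was lost without WT-wt replicate 1 (adjusted p = 0.822) and without HET-het replicates 1 and 2 together (adjusted p = 0.161), the libraries with the highest Hspa1b. The handling stress list turned downward without passing with the marker covariate (adjusted p = 0.655). The proliferating chondrocyte and hypoxia lists then did not pass either (adjusted p = 0.755 and 0.223).

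The remaining lists that passed, all downward, in HET-het against WT-wt had 0 members called over all genes. Other Polycomb-bound regulators had 1 of 51 lower adjusted over the list alone, Tbx5 (camera adjusted p = 0.00271, and adjusted p = 0.431 with an estimated correlation), a call lost without WT-wt replicate 1 (adjusted p = 0.0512). Noncanonical imprinted genes had 2 of 15 lower adjusted over the list alone, Prox1 and Enc1 (camera adjusted p = 0.0457, and adjusted p = 0.497 with an estimated correlation). The call was lost without WT-wt replicate 2 or HET-het replicate 2 or 3 (adjusted p = 0.216, 0.0568 and 0.0787). Skeletal muscle genes had 2 of 12 lower adjusted over the list alone, Ttn and Neb (camera adjusted p = 0.0457, and adjusted p = 0.413 with an estimated correlation), lost without WT-wt replicate 1, 3 or 4 (adjusted p = 0.111, 0.0974 and 0.0501). FGF genes had 0 of 18 adjusted over the list alone (camera adjusted p = 0.0457, and adjusted p = 0.547 with an estimated correlation), lost without WT-wt replicate 1, HET-het replicate 4 or HET-hom replicate 3 (adjusted p = 0.343, 0.229 and 0.0535). The Polycomb-bound, muscle and FGF lists did not pass with the marker covariate (adjusted p = 0.308, 0.308 and 0.615). The PRC2 list, which holds Eed, did not pass camera (adjusted p = 0.112) but passed fry (adjusted p = 0.0300). Of the lists that did not pass camera, the median and mean differed in sign for fibroblast genes (0.01 and -0.13), for PRC1 genes (-0.01 and 0.00) and for BMP genes (-0.01 and 0.03).

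The 2 comparisons that involve HET-hom called 448 genes in the same direction, 157 higher and 291 lower, and 1 in opposite directions. Independent calls would share 8.05 genes higher and 19.1 lower. Because both comparisons use the same HET-hom libraries, the overlap was also counted in data simulated without group effects, where it averaged 0.05 genes in 20 simulations, a value that leaves out the overlap that real effects bring. When the HET-hom libraries were divided so that each comparison used a different pair, 2 to 57 genes were shared over the 6 assignments. Cdkn1c, Slc38a4, Enc1, Scn9a, Shox2, Ccne1 and Prelp were higher, and Clic5, Dusp6, Bmp3 and Ndrg1 lower, in both comparisons. HET-hom against WT-wt and HET-het against WT-wt shared 1 gene in the same direction, Eed, and 1 in opposite directions, Inka2. A test of any difference among the 3 groups called 1216 genes, or 502 with libraries of a shared leading number summed and 600 with that number as a random block. It called 678 and 707 without HET-het replicates 1 and 3, and 463 and 474 without HET-hom replicates 2 and 4.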

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

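The tests in this part were chosen after the results they address were seen, except the test of fewer non-cartilage cells for X-linked genes.

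Endothelial and fibroblast markers were lower in HET-hom by camera with its preset correlation, but not with an estimated correlation (endothelial adjusted p = 0.383 against HET-het and 0.244 against WT-wt, fibroblast adjusted p = 0.406 and 0.293). For HET-hom against HET-het an equal loss of all non-cartilage tissue as the whole cause is not settled. The immune list, picked after the values of all lists were seen, goes against it. Relative to the mean log2 level of immune genes that of endothelial genes differed by -0.7044, at immune shares of 32.9 ± 4.40 and 32.7 ± 3.16 CPM (exact permutation p = 0.0286, the smallest possible, with all tested genes and with those of at least 1 CPM). That p carries no correction for the choice of lists, so it cannot decide the question. A test of unequal change over the lists, immune included, passed there in 2 of 4 choices of genes and lists (exact permutation p = 0.0286 to 0.0857). Against WT-wt such a loss stays open as well. Relative to immune genes, fibroblast genes differed by 0.4007 (exact permutation p = 0.0286) but endothelial genes by -0.0284 (exact permutation p = 0.886). The test over the lists passed in 0 of 4 choices (exact permutation p = 0.0571 to 0.0857). An equal loss beside a separate change of immune cells stays open, since immune genes also differed by -0.89 between HET-het and WT-wt, and without them a test of unequal change over the other lists, made in 4 choices of genes and lists, passed in 1 against HET-het (exact permutation p = 0.0286 to 0.08571) and in 0 against WT-wt (exact permutation p = 0.0857 to 0.1714). The libraries at the ends of the endothelial range, WT-wt replicate 1 and HET-hom replicate 4, carry a part of the pattern but not all of it: without them the median log2 fold change of the endothelial list against WT-wt went from -0.95 to -0.5622 and it stayed called with camera's preset correlation. A loss of some kinds of tissue in dissection or digestion stays open, with the osteoblast, endothelial and adipocyte shares at 0.614, 0.624 and 0.534 and the Schwann cell share at 1.24 of HET-het, as do, untested, an effect of oocyte EED loss on these cell types and a difference between litters.

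Noncanonical imprinted genes were higher in HET-hom by camera with its preset correlation, but not with an estimated correlation (adjusted p = 0.278 against HET-het and 0.293 against WT-wt). A trend with GC content or transcript length as the cause is argued against, since 5 of the 5 genes called against HET-het stayed called with offsets for both. Less non-cartilage tissue in HET-hom stays open: with the endothelial and immune covariate the median log2 fold change of these 5 went from 0.54 to 0.45. The median of their single-gene standard errors rose from 0.0955 to 0.104, and 2 stayed called, Slc38a4 and Enc1. Against WT-wt the whole list lost its upward call with that covariate (camera adjusted p = 0.962). An effect of oocyte EED loss on this list stays open and was not separately tested.

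X-linked genes leaned upward in HET-hom. Against HET-het 34 of 708 X-linked genes rose and 14 fell, compared with 609 and 719 of 20527 autosomal genes (Fisher's exact p = 0.000990), and against WT-wt 22 rose and 9 fell, compared with 243 and 554 (Fisher's exact p = 1.15e-05). Fisher's test counts genes as independent units, which genes of the same libraries are not, so its p does not measure the spread between libraries. A shift of the whole chromosome stays open: X ranked 1 of 20 chromosomes by its median shift of 0.04 against WT-wt, and the medians per library separated HET-hom from WT-wt (exact permutation p = 0.0286, the smallest possible) but not from HET-het (exact permutation p = 0.0571). Fewer non-cartilage cells as the cause is argued against only for the median shift and only for endothelial and immune cells. Against HET-het, which that shift did not separate from HET-hom, it was 0.0392 without and 0.04162 with the marker covariate. Fewer cells of other non-cartilage types stay open as the cause, since the covariate holds endothelial and immune markers alone. For the called genes fewer non-cartilage cells of any type stay open, since directions of these genes were not counted with the covariate. An effect of oocyte EED loss on X-linked genes stays open and was not separately tested.

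Whether chance could give such counts was tested by other splits of the same libraries. For HET-hom against HET-het 1 of 35 splits, the real one, gave as many changed genes (1385, highest other 1), for HET-hom against WT-wt 1 of 35 (837, highest other 1), for HET-het against WT-wt 1 of 35 (8, highest other 4), and for any difference among the 3 groups 1 of 100 (1216, highest other 683). Only if the libraries were exchangeable would these splits argue against chance for these counts of genes, with 1 of 35 the smallest share that 35 splits can give. The split with 683 kept the 4 HET-hom libraries together and mixed the others. The 2 libraries of each group that share a leading number are not shown to be independent. With that number as a random block their consensus correlation was 0.34. Of the 35 splits 7 keep them together, too few for a share under 0.05, so these 7 cannot exclude chance. In them the highest other counts were 0, 1 and 3 in the order above, where summing such libraries left 573, 520 and 3 changed genes. Chance cannot be excluded for the counts of lists past camera with its preset correlation, which 8 of 35 splits reached for HET-hom against HET-het (12, highest other 17), 16 of 35 for HET-het against WT-wt (10, highest other 16) and 5 of 35 for HET-hom against WT-wt (19, highest other 23).

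Single libraries lay far from the other 3 of their group by Dixon's test in 21 of 357 groups of values, where chance gives about 1 in 20. In HET-hom replicate 3, Bcl6 was at 5.65 CPM (others 13.4 to 14.9), Gbp7 at 7.23 (4.41 to 4.71), Sfrp5 at 31.8 (38.5 to 39.3) and Sox10 at 5.00 (8.91 to 9.25). HET-hom replicate 4 held Scn9a at 3.41 CPM (2.23 to 2.41), Smoc1 at 126.6 (107 to 109.5), Rpl22l1 at 20.2 (27.4 to 28.2) and a keratinocyte share of 13.1 (10.4 to 10.7). Sfmbt2 was at 17.2 CPM (13.9 to 14.3) and the mitochondrial share at 7128 (4802 to 5117) in HET-hom replicate 1, and Xlr3b at 0.729 (0.646 to 0.659) in HET-hom replicate 2. In WT-wt replicate 1 Clic5 was at 2.82 CPM (2.47 to 2.53), Igfals at 1.26 (2.35 to 2.45) and Sfrp2 at 97.8 (66.4 to 69.5). The other WT-wt values were Dusp6 at 69.5 CPM in replicate 3 (58.6 to 59.3), Sox10 at 5.27 in replicate 4 (6.45 to 6.66) and a ribosomal protein share of 15643 in replicate 2 (18341 to 18758). Among HET-het libraries replicate 1 held Xist at 2488 CPM (2674 to 2677) and Sfrp5 at 33.3 (25.3 to 26.2), and replicate 4 held Lef1 at 30.5 (34.6 to 34.8) and Oplah at 22.4 (26.5 to 27.3).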

How the results depend on the processing

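The alternatives chosen after the data were seen were the endothelial and immune marker covariate, offsets for GC content and length, and the 2 pairs of libraries left out together.

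Over 6551 values of named genes under alternatives, 5206 kept their direction and side of the threshold, 1121 lost the call, 217 gained it and 7 turned direction. RLE and upper quartile scaling and a stricter filter moved none of the counts of changed genes by over 1.5 times. The 1385 genes of HET-hom against HET-het became 2117 with DESeq2, 4712 with 24 lanes as samples, 573 with libraries of a shared leading number summed, 726 with that number as a random block, 403 with the marker covariate (378 shared) and 372 without HET-het replicates 1 and 2. Leaving out 1 library gave 638 to 1753 (658, 729 and 712 without HET-het replicates 1, 2 and 3, and 638 and 665 without HET-hom replicates 2 and 4). The 837 of HET-hom against WT-wt became 1582, 4096, 520, 447, 0 (1590 at an unadjusted p under 0.05) and, without WT-wt replicate 1 and HET-hom replicate 4, 183, and 419 with the 8 libraries compared. Leaving out 1 library gave 219 to 1203 (477, 467 and 478 without WT-wt replicates 1, 3 and 4, and 329 and 219 without HET-hom replicates 2 and 4). The 8 of HET-het against WT-wt became 154, 1459, 3 and 5 in the first settings, 93 without a filter, 17 with GC and length offsets, 16 without WT-wt replicate 1 and HET-hom replicate 4, and 3 to 13 without 1 library (13 without WT-wt replicate 2, 3 without WT-wt replicate 3 or 4 or HET-het replicate 3, and 5 without HET-het replicate 2). The 1216 of any difference became 2382, 6055, 502, 600, 335 with the covariate, 550 and 651 without the 2 pairs, and 463 to 1669 without 1 library (678 and 707 without HET-het replicates 1 and 3, and 463 and 474 without HET-hom replicates 2 and 4). Lanes as samples treat repeats of 1 library as animals. Summed or omitted libraries leave fewer samples, and for the other changes the cause was not tested.

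Leaving out HET-het replicates 1 and 2 kept 99.4% of the 1385 genes in sign and at 50% of their size or more, and 339 in the calls, and the other 5 pairs of HET-het libraries left 168, 346, 229, 304 and 674.

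Eed in HET-hom against HET-het (0.26) lost its call at 0.26 with limma voom, without a filter, with summed libraries and with the random block, at 0.25 with 8 libraries, 0.30 and 0.21 with lane 1 and lane 2 alone, 0.30 with the covariate, 0.23 with offsets, 0.28 and 0.27 without the 2 pairs, and 0.21 to 0.29 without 1 library. Against WT-wt it lost its call at -0.26 with the covariate and -0.33 without WT-wt replicate 1 and HET-hom replicate 4, with -0.36 to -0.31 without 1 library. The cause was not tested.

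Lists past camera went from 12, 10 and 19 to 1, 0 and 0 with an estimated correlation and 4, 2 and 10 with fry (HET-hom against HET-het, HET-het against WT-wt, HET-hom against WT-wt), to 8 for the last with the covariate, and HET-het against WT-wt ran from 6 (without WT-wt replicate 1) to 13. With the covariate, which is built from the endothelial and immune lists, log2 fold changes of HET-hom against WT-wt turned positive for Fabp4 (0.0115), Tek (0.0463), Col1a1 (0.0557), Col1a2 (0.13), Tnfrsf11a (0.17), Gata2 (0.00404) and Col3a1 (0.0618). Lists turned too, with adjusted p for HET-hom against WT-wt of 0.428 (resting), 0.993 (proliferating), 0.891 (osteoblast), 0.962 (osteoclast and noncanonical imprinted), 0.818 (fibroblast, Wnt and interferon), 0.0494 (endothelial) and 0.0767 (hypoxia), for HET-hom against HET-het of 0.801 (proliferating) and for HET-het against WT-wt of 0.655 (immediate early). Genes shared by the calls of both comparisons with WT-wt went from 1 to 12 at an adjusted p under 0.1.

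With the replicate number as a block, counts were 1331, 9 and 935 in the same order, 1216 for any difference and 14, 10 and 19 lists, and Eed in HET-hom against HET-het lost its call at 0.26. Whether the numbers pair libraries is not settled: same-numbered libraries of different groups correlated at -0.31 to 0.27, and 4 of 12 pairs exceeded 0.1. Of the 12 libraries 6 correlated best with their own number in another group. Libraries sharing a leading number correlated at -0.04 to 0.17, against a median of -0.38 for other pairs of a group. These are deviations from the group mean, which within a group correlate below 0 on average by construction. Libraries sharing a leading number were thus more alike than other pairs. With that number as a random block their consensus correlation was 0.34.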

Other observations

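The heat shock genes Hspa1a and Hspa1b, named after their values were seen, and Hspb1 stood apart in 2 HET-het libraries. Hspa1a was at 222 and 94.5 CPM in HET-het replicates 1 and 2 and at 2.24 to 20.1 CPM in the other 10 libraries, and Hspb1 was at 26.3 and 10.2 CPM against 1.92 to 5.07. In HET-hom against HET-het the log2 fold change was -3.75 for Hspa1a and -4.07 for Hspa1b, and neither passed (edgeR adjusted p = 0.0764 and 0.0739). These 2 libraries share a leading number in their names.

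Fold changes of all 21788 genes in the comparisons of HET-hom with HET-het and with WT-wt correlated at 0.67 across genes, which are not independent replicates. Comparisons that share a group correlate without any effect, at 0.50 in simulated data, and these at 0.31 to 0.40 when each used a different pair of HET-hom libraries. Their covariance was 0.0829, against 0.0282 in the simulated data. The first 3 principal components of the 12 libraries took 22.2%, 12.8% and 11.3% of the variance.

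Several well-known genes of cartilage, PRC2 and growth, all chosen after their values were seen, did not pass in HET-hom against HET-het. The log2 fold change was 0.23 for Ihh (edgeR adjusted p = 0.680), 0.33 for Col10a1 (adjusted p = 0.705), -0.22 for Col2a1 (adjusted p = 0.359), 0.17 for Ezh2 (adjusted p = 0.132), 0.13 for Suz12 (adjusted p = 0.139) and -0.09 for Igf2 (adjusted p = 0.606).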
